A study of Danio rerio with 33 samples.

How the data were processed

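Poly(A) RNA of zebrafish brain, liver and muscle was sequenced from stranded libraries, per the labels' protocol, in 9 groups: 3 tissues of acromegaly (3 libraries each), wild type (3) and aged fish (5), 33 libraries. Reads were aligned with HISAT2 and assembled and quantified with Cufflinks on GRCz10, per the submitters' processing notes. The deposited table held 1 estimated count per gene and group, per the file headers, and not 1 per library. It also held 1 FPKM per gene and group, per the file headers, although the file's name says RPKM. Coordinates are those of the table, on GRCz10 and 1-based.

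Of 38886 rows, 4710 carried no gene name, 1262 named more than 1 gene and 13090 shared a locus with another row. In 6159 rows the end minus the start equalled the transcript length. Estimated counts below 4 (groups of 3 libraries) or below 1 (groups of 5) were whole-number combinations of 3 or 5 steps, 1 per library, within 1.2e-05, in 100% of cases (at most 3.40% of random values), so each value pools its libraries. The steps gave the depth per library. They also gave a spread between libraries from values of 3 to 10 in the groups of 3: overdispersion of 0.372 and 0.348 in brain, 0.557 and 0.369 in liver, and 0.507 and 0.518 in muscle (acromegaly, wild type). Where values of 1 to 60 are called whole multiples of the step of 1 library, they were multiples of at least 3 fragments within 8e-06 below 10 and within 8e-05 from 10 on, plus 2e-07 per fragment. Tested on simulated data made with 0.4, the step for the spread returned 0.334, which is low. Because low values may vary more than high ones, chance levels are given with this spread at every gene and with counting error alone. No spread was read for aged groups, which were given the mean of the acromegaly and wild-type spreads of their tissue.

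The planned tests were moderated linear models per gene, an interaction test across tissues and a competitive test of gene lists. All need values per library and could not be run on pooled values. Instead log2(FPKM + 1) was subtracted between groups, for genes with FPKM of 1 or more in at least 1 group of the tissue, and genes at least 2-fold apart were counted. The 95% counting interval beside a named gene covers the sampling of fragments only. For each of 50 gene lists, fixed from general knowledge before the data were examined, the median over kept members (at least 5) was set against 10000 random lists matched on 20 bins of expression. A list was called higher or lower when its median lay outside the central 95%. Genes are not independent, so these percentiles are not tests of the conditions.

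Acromegaly and aged fish were each compared with wild type and with each other in each tissue. For the 2 comparisons that share wild type, the correlation, covariance and overlap were set against 100 simulated draws of unchanged groups. For liver, acromegaly against wild type (16767 genes), simulated data with the low-value spread put 42% of genes set 2 times higher, 86% of those set 4 times higher and 96% of those set 8 times higher at least 2-fold higher, and 72% of those set at 0.25 times at least 2-fold lower. Of unchanged genes 14.0% were at least 2-fold apart. Lists shifted by 0.5 were found in 86% of cases, and 5% of unchanged lists lay outside. With counting error alone the shares were 34%, 100%, 100% and 100%, then 1.29%, 100% and 5.5%. The unchanged lists were drawn at random with spread independent between genes, so their share near 5% was set by construction. It is not the rate for lists whose genes vary together.

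Named genes were hspa5, xbp1, atf4a, ddit3, atf6, gh1, igf1, socs2 and cdkn1a, the 5 genes furthest apart in each direction (3 for acromegaly against aged), and up to 4 members of each list outside the central 95% or with at least 3 members at least 2-fold apart, at FPKM of 5 or more in the higher group. This rule was adapted after the data were seen. Its adjusted p and its demand for no overlap between libraries could not be applied. A transcript of at least 300 nucleotides and 20 fragments were required instead, and for the furthest genes a row naming 1 gene. Genes named across all tissues, kidney, gonad and immunoproteasome genes were chosen after their values were seen. The lists of kidney genes and of clock genes high after dawn or dusk were also written then.

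Alternatives planned and run were a pseudocount of 0.1, no filter, and median-of-ratios scaling. Alternatives chosen after seeing the data were estimated counts (pseudocount and floor of 10), a floor of 5, a GC correction in 20 bins, and rows naming 1 gene. The GC correction left out rows with a very short transcript or none. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.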

Results

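Messenger RNA was sequenced from brain, liver and muscle of zebrafish in 3 conditions: a zebrafish model of acromegaly and wild type, both 1 year old, and aged fish of 3 years. Acromegaly is a disease of growth hormone excess. By its title, the series concerned the unfolded protein response (UPR) in acromegaly. The UPR is the response of cells to unfolded proteins that build up in the endoplasmic reticulum (ER). It was read here only through levels of transcripts. Each tissue had 3 acromegaly, 3 wild-type and 5 aged libraries, 33 in all. The deposited table held 1 pooled value per tissue and condition for 38886 rows, most of them single genes. Differences therefore have no replicate check, no p-value is given, and every level below is the authors' pooled FPKM. The estimated counts summed to 2.27 M, 2.46 M and 2.497 M in brain (acromegaly, wild type, aged), to 6.22 M, 4.54 M and 3.71 M in liver, and to 7.21 M, 5.67 M and 6.17 M in muscle. The steps between low values implied between 1.17 M and 7.25 M fragments per library. Genes with FPKM of 1 or more in at least 1 condition were kept: 18644 in brain, 16767 in liver and 15921 in muscle. At least 2-fold means a difference of 1 or more in log2(FPKM + 1), and pairs of FPKM are given with the first-named condition first.

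Growth hormone was read first, since the model is defined by it. The row of zebrafish gh1 (chromosome 3, 22197190 to 22202365) held 123 FPKM in acromegaly brain, 50.7 in wild-type brain and 3.78 in aged brain. In liver and muscle it was listed at 0 in acromegaly and at no more than 0.272 FPKM in any other group. The labels do not say which growth hormone gene the model carries, so this row checks them only in part. The list of pituitary genes was also higher in acromegaly brain and lower in aged brain than in wild type, as given below. The gh1 level in brain may therefore follow the amount of pituitary in the samples, which was not tested. Downstream of the hormone, igf1 (in a row that also names nup37) was 68.8 against 29.0 FPKM in acromegaly against wild-type liver, and the feedback inhibitor gene socs2 was 4.75 against 1.97. The related inhibitor gene cishb was 14.4 against 3.56 FPKM in the same livers. Of the 27 kept members of the growth hormone and IGF list, 5 were at least 2-fold higher in acromegaly liver and 0 lower, with a median log2 difference of 0.22, inside the central 95% of matched random lists.

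In acromegaly liver, ER chaperones and folding enzymes were higher than in wild type as a list, while the other 3 UPR lists lay inside the random lists with FPKM. With estimated counts, tried after seeing the data, PERK targets (0.35) and ER-associated degradation (0.25) lay above them too. In liver, hspa5 (chromosome 5, 2440428 to 2449011), the ER chaperone BiP, was 66.5 against 21.8 FPKM, 3.04-fold higher (log2 difference 1.56, 95% counting interval 1.44 to 1.69). The transcription factor gene xbp1 (chromosome 5, 15444194 to 15448703), whose product drives ER chaperone and secretory genes, was 291 against 96.2 FPKM, and the sensor gene atf6 (chromosome 20, 33906261 to 34017141) was 14.5 against 3.50. The stress transcription factor genes atf4a (45.8 against 40.6 FPKM) and ddit3, which encodes CHOP (22.9 against 17.4), were less than 2-fold apart. Of 35 kept ER chaperone and folding enzyme genes, 8 were at least 2-fold higher and 1 lower. Besides hspa5, the co-chaperone gene dnajc3a (62.7 against 19.8) and the prolyl isomerase gene fkbp11 (88.0 against 32.2) were higher, and the oxidase gene ero1a was lower (6.44 against 24.3). The list median was 0.53, above all 10000 matched random lists, whose central 95% reached 0.25. In aged liver hspa5 (63.1 against 21.8) and atf6 (17.1 against 3.50) were also higher than in wild type, xbp1 was 156 against 96.2, and the chaperone median was 0.34 (percentile 99.3). The targets of the PERK arm had medians of 0.24 in acromegaly liver (percentile 94.5, inside the band) and 0.35 in aged liver (percentile 98.2, but 97.2 and inside the band after a GC correction). The glutathione-degrading enzyme gene chac1 of that list was 414 against 90.4 FPKM in acromegaly and 377 against 90.4 in aged against wild-type liver. UPR sensors and transcription factors (0.22) and ER-associated degradation (0.23) stayed inside the band in acromegaly liver, although xbp1 and atf6 belong to the sensor list.

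In acromegaly brain, hspa5 was 31.8 against 26.7 FPKM, xbp1 53.8 against 47.5, atf4a 23.9 against 22.8, ddit3 11.9 against 10.99 and atf6 6.35 against 5.65, and none of the 4 UPR lists lay outside the band of random lists. In aged brain hspa5 (15.1 against 26.7) and atf4a (10.2 against 22.8) were lower than in wild type, and the 4 UPR lists again lay inside the band, with medians from -0.29 (ER-associated degradation, -0.46 and below the band at a floor of 5 FPKM) to 0.27. In muscle, hspa5 was 59.24 against 35.7 in acromegaly and 57.6 against 35.7 in aged against wild type, xbp1 was 85.2 against 50.2 and 76.8 against 50.2, and ddit3 was 35.0 against 20.7 and 19.7 against 20.7. The chaperone medians in muscle were 0.14 and 0.17, inside the band. Whether the acromegaly and wild-type tissues differed more in liver than in brain or muscle was not tested.

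**Figure D1:**
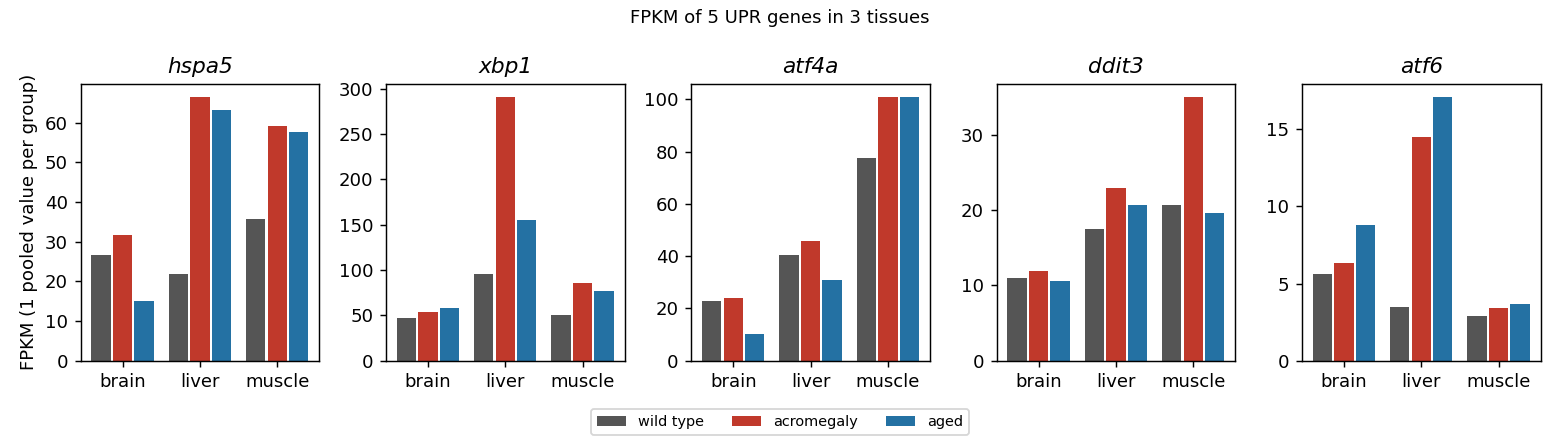
Pooled FPKM of hspa5, xbp1, atf4a, ddit3 and atf6 (y axis, starting at 0) in brain, liver and muscle (x axis) of wild type (grey), acromegaly (red) and aged fish (blue), 1 value per bar with no error. In liver, hspa5 stood at 66.5 FPKM in acromegaly, 63.1 in aged and 21.8 in wild type.

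**Figure D2:**
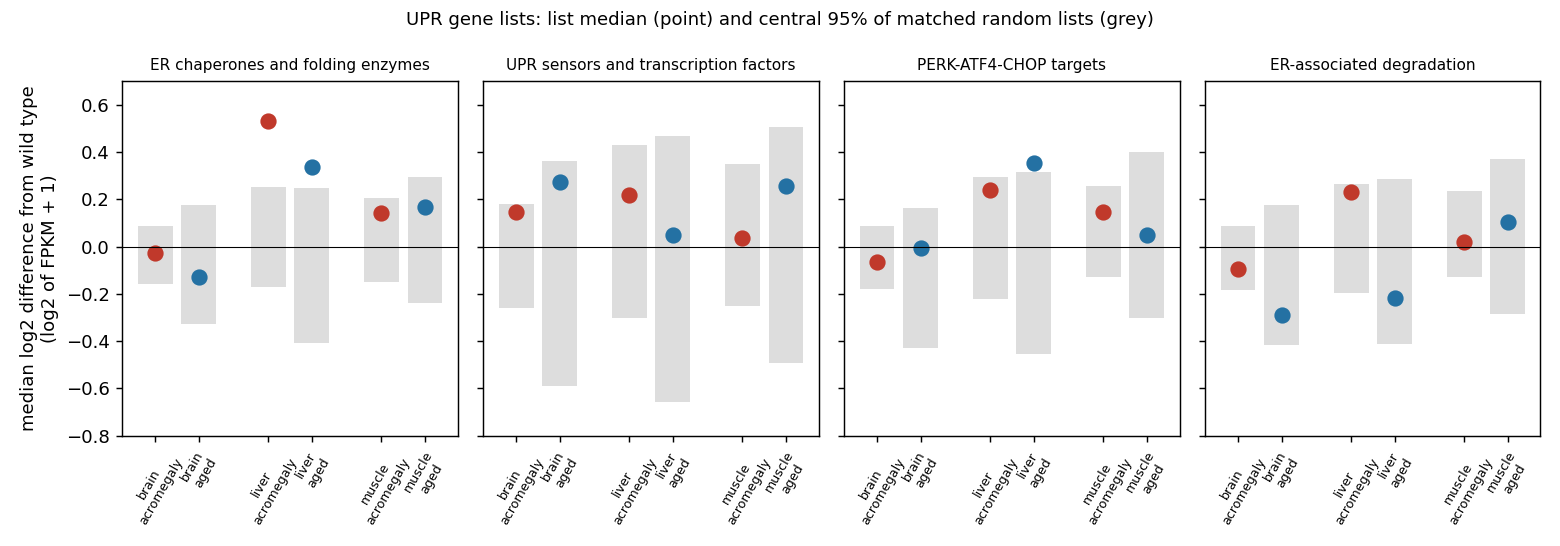
Median log2 difference from wild type (y axis) of 4 UPR gene lists in each tissue for acromegaly (red points) and aged fish (blue points), with the central 95% of 10000 random lists matched on expression (grey bars). The chaperone medians of 0.53 in acromegaly liver and 0.34 in aged liver, and the PERK target median of 0.35 in aged liver (inside them after a GC correction, at 0.29), lie outside the bars.

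Beyond the UPR, acromegaly liver had higher levels of genes for translation, protein export, cholesterol and fat synthesis, and egg yolk. The yolk precursor gene vtg2 (chromosome 22, 24842066 to 24853200) was 27561 against 8.38 FPKM and vtg3 3105 against 0.901, and the estrogen receptor gene esr1, which controls them, was 114 against 1.41. Rows naming vitellogenin genes took 14.1% of the estimated counts in acromegaly liver, 3.79% in aged and 0.0301% in wild-type liver. The labels give no sex. More egg-yolk-producing females in a group therefore cannot be told apart from its condition for any gene in these livers. Of 62 ribosomal protein genes 59 were at least 2-fold higher (median 1.33), among them rps20 (14498 against 1426) and rplp0 (8133 against 2268). ER translocation and secretory transport genes had 8 of 42 at least 2-fold higher, such as the translocon gene sec61a1 (444 against 131) and ssr2 (648 against 215). In cholesterol synthesis 14 of 22 genes were at least 2-fold higher (median 1.32), with the rate-limiting enzyme gene hmgcra at 29.2 against 0.796 and sqlea at 13.5 against 0.182. Lipogenic genes (median 0.37, inside the band without a filter at 0.24 and at a floor of 5 FPKM at 0.25) included scd, a fatty acid desaturase (219.8 against 10.9), acaca, acetyl-CoA carboxylase (140.4 against 18.3), and fasn, fatty acid synthase (25.2 against 3.03). The rate-limiting bile acid enzyme gene cyp7a1 was 38.3 against 5.03, and the gluconeogenic genes g6pca.2 (970.4 against 186) and pck1 (780.1 against 224) were higher, while the list of gluconeogenesis and glycolysis was lower (median -0.26). Fatty acid oxidation genes were lower (32 of 38 below wild type, 2 at least 2-fold, median -0.47), including the lipid-sensing receptor gene pparaa (9.92 against 25.7). Interferon-response genes (median -0.36), such as rsad2 (19.5 against 51.9) and isg15 (18.3 against 47.6), and cell cycle genes (median -0.44), such as cdk1 (2.93 against 7.82), were lower. The cell cycle inhibitor gene cdkn1a was 2.52 against 10.6.

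Markers of other cells also differed between these livers. Macrophage genes were higher (8 of 21 at least 2-fold, median 0.77), with the scavenger receptor gene marco at 49.5 against 6.53. Complement and acute phase genes had a median of 0.61 (inside the band at a floor of 5 FPKM), and crp was 459 against 56.0. Endocrine pancreas genes were lower (median -1.21), with ins, the insulin gene, at 497 against 1546. The exocrine pancreas median was -0.05, inside the band. Germ line and oocyte genes had a median of 1.501, with the egg coat gene zp3b at 11.8 against 0.0980. In total 1310 genes were at least 2-fold higher and 826 lower in acromegaly liver. Of 48 lists 20 lay outside the band, where 5% would be 2.4 for lists of independent genes. Simulated groups with no difference, given at every gene the spread read from low values, put 2336 genes at least 2-fold apart, and counting error alone put 205. The total of 2136 is therefore not a count of genes that differ between the conditions.

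In aged liver, genes of the exocrine and endocrine pancreas were lower than in wild-type liver, and immediate early, macrophage, neutrophil, inflammatory and acute phase genes were higher. All 19 kept exocrine pancreas genes were at least 2-fold lower (median -5.97), with the elastase gene ela2l at 6.73 against 6552 FPKM, and 8 of 10 endocrine genes were too, with ins at 16.3 against 1546. The summed FPKM of exocrine pancreas genes was 99894 in wild-type, 91959 in acromegaly and 1371 in aged liver. These genes mark pancreas tissue in the samples, so their fall cannot be read as a change of liver cells. Other genes far lower in aged liver were the chitinase genes chia.3 (6.35 against 10885) and chia.1 (2.56 against 5125), the lipid carrier gene fabp1b.1 (39.7 against 10771) and the apolipoprotein gene apoa1a (192 against 21167). Inflammatory mediators were higher (9 of 23 at least 2-fold), such as il1b (6.06 against 0.564) and irg1 (16.5 against 0.932), the latter encoding the itaconate-producing enzyme of macrophages. The acute phase genes hp (452 against 27.6), hamp, the iron hormone hepcidin (828 against 69.1), and saa (64.7 against 5.81) were higher with 10 of 26 members of their list. Macrophage (median 1.41) and neutrophil genes (median 1.204) were higher, with grn2 at 349 against 42.5 and the myeloperoxidase gene mpx at 44.2 against 4.01. Within the growth hormone and IGF list (median 0.70), the IGF-binding protein genes igfbp1a (1045 against 38.4) and igfbp1b (189.7 against 1.22) and the inhibitor gene socs2 (23.5 against 1.97) were higher, and igf1 was 21.6 against 29.0. Amino acid enzymes were higher (median 0.69), with the tyrosine aminotransferase gene tat at 1505 against 99.7. Fatty acid oxidation was lower (19 of 38 genes at least 2-fold), for example the mitochondrial carnitine transferase gene cpt1b (5.93 against 105). Oxidative phosphorylation (median -0.79) and erythrocyte genes (median -1.54) were lower as well. Of the immediate early genes, which respond within minutes to stimulation, 13 of 20 were at least 2-fold higher, with fosab at 202 against 5.87. vtg2 was 4413 against 8.38 and esr1, read here after its values were seen, was 4.25 against 1.41. In total 2508 genes were at least 2-fold higher and 2026 lower, against 1281 in the simulation of unchanged groups with the spread of the low values. That simulation assumed for aged fish the mean spread of the acromegaly and wild-type groups, since none was read for them. At a floor of 5 FPKM, chosen after seeing the data, the balance turned to 1341 higher and 1454 lower. The difference was correlated with the GC content of the transcript (r = -0.22 across 16614 genes).

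In acromegaly brain, pituitary, extracellular matrix and immediate early genes were higher, and myelin and oxidative phosphorylation genes were lower. The pituitary hormone genes prl, prolactin (39.0 against 7.14 FPKM), and smtlb, somatolactin (60.2 against 20.2), were higher along with gh1, whereas smtla was lower (6.68 against 19.4). The pituitary list had a median of 0.48 over 13 genes, which may follow the amount of pituitary in the samples and was not tested. Matrix genes had 10 of 33 at least 2-fold higher (median 0.66), among them the fibrillar collagen genes col1a1a (30.4 against 5.85) and col1a2 (21.9 against 5.14) and the proteoglycan gene lum (14.9 against 0.393). The immediate early gene npas4a, induced by neuronal activity, was 45.1 against 9.17, and 24 of 26 members of its list were above wild type. Myelin genes were lower in 18 of 20 cases, 1 by at least 2-fold: myrf, the master regulator of myelin genes (5.69 against 13.9). Oxidative phosphorylation was lower in 67 of 71 genes, 0 of them at least 2-fold (median -0.31). The single genes furthest below wild type included rho, the rhodopsin gene (0 against 45.7), gngt1 (0.0564 against 10.8), pde6h (2.35 against 22.6) and the peptide gene urp1 (3.56 against 32.8). Markers of tissues outside the brain differed beside these groups. Exocrine pancreas genes were higher (median 1.41, prss59.1 17.7 against 2.57), as were hepatocyte (median 0.39, although their summed FPKM was 530.3 against 518), neutrophil (median 0.57, lyz 113 against 10.9) and skin genes (median 0.73). Fast muscle (median -0.76) and slow muscle genes (median -0.70) were lower. The immunoglobulin genes ighv5-8 and ighv9-2 stood at 23.5 and 11.2 FPKM in acromegaly brain and were listed at 0 in wild type. In total 549 genes were at least 2-fold higher and 408 lower, fewer than the 1667 of the simulation with the spread of the low values and more than the 126 of counting error alone.

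Aged brain held lower levels of pituitary, muscle, ribosomal and oxidative phosphorylation genes than wild-type brain. Of 13 pituitary genes 10 were at least 2-fold lower (median -3.43): pomca, the precursor of corticotropin, was 1.04 against 157, the gonadotropin subunit gene lhb 2.63 against 153, and gh1 3.78 against 50.7. Fast muscle genes had a median of -2.44, with the creatine kinase gene ckma at 3.45 against 117, and their summed FPKM was 69.4 against 780. Pituitary and muscle genes may follow the amount of those tissues in the samples, so their fall cannot be read as a change of brain cells. Ribosomal protein genes were at least 2-fold lower in 37 of 62 cases (median -1.18), such as rpl26 (72.4 against 370.1), and oxidative phosphorylation genes in 25 of 71, such as atp5a1 (58.3 against 303) and cox5ab (18.99 against 117). The glycolytic gene gapdh was 4.999 against 134, and proteasome genes were lower (median -0.51, psma1 7.79 against 40.9). Myelin genes had 6 of 20 at least 2-fold lower, with mbpa, myelin basic protein, at 2754 against 9036, and srebf2, which drives cholesterol synthesis, was 0.773 against 19.7. Endothelial genes were lower (median -0.66), with the angiopoietin receptor gene tek at 0.455 against 5.30. The neurogenesis list was lower (median -0.61, inside the band at a floor of 5 FPKM). Its single genes went both ways, with eomesa at 1.301 against 9.73 and tuba1a at 55.8 against 9.24. Higher in aged brain were clock genes (15 of 29 at least 2-fold, median 1.03), led by per3 (chromosome 11, 39694894 to 39756936; 29.6 against 0.555) and the repressor gene ciarta (16.5 against 1.03), and the immediate early genes npas4a (56.1 against 9.17) and fosb (5.87 against 1.23). In total 1986 genes were at least 2-fold higher and 1797 lower, against 1062 in the simulation with the spread of the low values, and the balance turned to 705 and 1173 at a floor of 5 FPKM and to 1098 and 1360 for rows naming 1 gene (both chosen after seeing the data). Across 18516 genes the difference was correlated with the GC content of the transcript (r = -0.31), where genes are not independent replicates.

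In acromegaly muscle, a fast myosin gene and immediate early, heat shock and macrophage genes were higher, and kidney, neutrophil, erythrocyte and most hepatocyte-list genes were lower. The myosin heavy chain gene myha was 1279 against 48.7 FPKM, and fast sarcomere genes had 5 of 26 at least 2-fold higher and 3 lower (median 0.63). The coagulation factor gene f13a1a.1 was 810.5 against 0.527 in acromegaly and 164 against 0.527 in aged against wild-type muscle. The immunoglobulin light chain row of igic1s1 was 136 against 2.52 in acromegaly muscle. Immediate early genes were at least 2-fold higher in 17 of 23 cases, among them the nuclear receptor genes nr4a3 (48.8 against 1.81) and nr4a1 (194 against 31.6). Cytosolic heat shock genes had a median of 0.54, with hsp70l at 10.04 against 1.22, and complement C1q genes of macrophages, such as c1qa (33.4 against 9.95), were higher. Matrix genes were higher by a median of 0.28 (0.17 and inside the band without a filter), with the growth factor gene ctgfa at 32.6 against 8.72. Autophagy genes were lower in 24 of 31 cases (median -0.27), 2 by at least 2-fold. Neutrophil genes were at least 2-fold lower in 10 of 16 cases (median -1.55; lyz, lysozyme, 89.2 against 776), erythrocyte genes in 8 of 14 (median -1.45; hbba2 23.6 against 460.1) and hepatocyte genes in 12 of 21 (median -1.04; apoc1 3.27 against 28.1). The summed FPKM of hepatocyte genes was not lower, at 817 in acromegaly, 730.04 in wild-type and 796 in aged muscle. Beside them, a list of kidney genes written after the data were seen had a median of -2.39 (37 of 41 at least 2-fold lower). Most of its members passed the filter through wild-type muscle, where 40 reached FPKM of 1, against 6 in acromegaly muscle. Among the genes behind the choice of that list was stc1l, a stanniocalcin gene, at 0.996 against 626. The amino acid enzyme genes pah (0.2495 against 22.7) and agxtb (0.278 against 14.0) and the antioxidant gene gpx1b (0.447 against 13.5) were lower too. In total 788 genes were at least 2-fold higher and 1201 lower, and the simulation with the spread of the low values gave 2347 at least 2-fold apart, with 139 from counting error alone.

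Aged muscle showed lower levels of genes for fat use and respiration than wild-type muscle and higher levels of heat shock and proteasome genes. Fatty acid oxidation genes were at least 2-fold lower in 24 of 37 cases (median -1.29), including ppargc1a, a coactivator of mitochondrial biogenesis (2.62 against 22.8), and acadvl (108 against 465). Oxidative phosphorylation (median -0.66, cox6b1 17.0 against 211), lipogenesis (median -1.06, plin2 0.809 against 7.501) and cholesterol synthesis (median -0.92, srebf2 0.733 against 6.19) were lower. The oxygen store gene mb, myoglobin (380.1 against 2817), and the slow myosin gene smyhc1 (192 against 656) were lower, as was the calcium pump gene atp2a1 (881 against 3691), while myha was 4472 against 48.7. Cytosolic heat shock genes had 12 of 24 at least 2-fold higher (median 1.12), with hsp70l at 27.0 against 1.22 and the small heat shock gene hspb11 at 1253 against 225. All 31 proteasome genes were above wild type, 8 by at least 2-fold, such as psmb6 (195 against 55.1). The muscle atrophy list stayed inside the band (median 0.10), with the ubiquitin ligase gene trim63a at 947 against 418 and foxo1a at 8.39 against 36.4. Clock genes (median 0.83, per1b 13.6 against 0.944) and immediate early genes (median 1.49, fosab 37.8 against 1.80) were higher, and synapse genes were too (median 1.13, snap25a 6.03 against 0.919). Neutrophil (median -1.01), erythrocyte (median -1.37), hepatocyte (median -1.37), exocrine pancreas (median -2.43) and kidney genes (median -2.39, 38 of 41 at least 2-fold lower) were lower than in wild-type muscle, with cdh17 at 0.789 against 63.2. In total 1640 genes were at least 2-fold higher and 1833 lower, against 1755 in the simulation with the spread of the low values, and a floor of 5 FPKM turned the balance to 1061 and 1018.

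**Figure D3:**
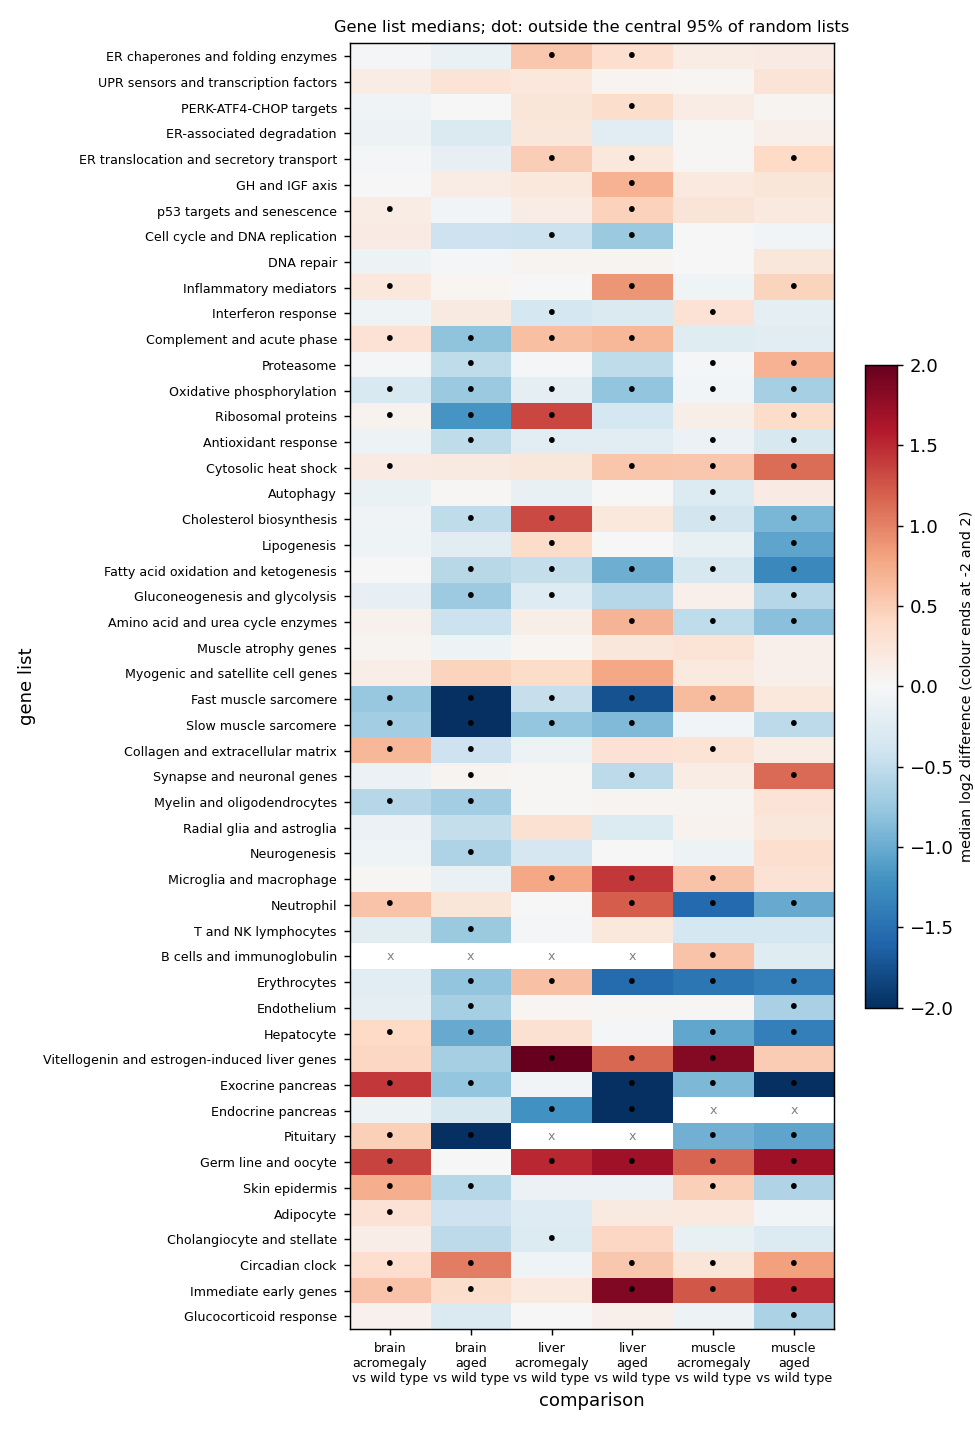
Median log2 difference from wild type (colour, ending at -2 and 2) of each gene list (rows) in each tissue and condition (columns), a dot marking medians outside the central 95% of 10000 matched random lists and an x marking lists with fewer than 5 kept members. Vitellogenin genes (2.07 in acromegaly liver) and exocrine pancreas genes (-5.97 in aged liver) reach the ends of the scale.

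Acromegaly and aged fish were also set against each other, since the aged group serves as a reference for ageing. In brain, acromegaly was higher in pituitary genes (median 4.33, gh1 123 against 3.78), ribosomal protein genes (40 of 62 at least 2-fold) and matrix genes (17 of 33), and lower in clock genes (median -0.49), with per3 at 0.934 against 29.6. hspa5 was 31.8 against 15.1 and atf4a 23.9 against 10.2. The ER chaperone median of 0.21 lay inside the band, but outside it after a GC correction (0.32) and with estimated counts (0.23). The other UPR medians for this comparison lay inside the band, except under added alternatives: ER-associated degradation in brain at a floor of 5 FPKM (0.48) and PERK targets in muscle after a GC correction (-0.33) and with estimated counts (-0.43). In liver, hspa5 (66.5 against 63.1) and atf6 (14.5 against 17.1) were close, and xbp1 was 291 against 156. Ribosomal (58 of 62 at least 2-fold), cholesterol (median 1.76), lipogenic (median 0.99) and exocrine pancreas genes (median 5.84) were higher in acromegaly, and immediate early (median -1.43) and inflammatory genes (median -0.53, inside the band at a floor of 5 FPKM at -0.36) lower. In muscle, hspa5 was 59.24 against 57.6, ddit3 was 35.0 against 19.7, fatty acid oxidation genes were higher in acromegaly (18 of 37 at least 2-fold, median 1.00) and proteasome genes lower (median -0.74). Genes at least 2-fold higher and lower in acromegaly numbered 1754 and 1774 in brain, 1900 and 2128 in liver, and 1349 and 1442 in muscle. At a floor of 5 FPKM the balance turned to 1039 and 580 in brain and to 1449 and 1014 in liver, and rows naming 1 gene gave 1351 and 947 in brain and 1584 and 1414 in liver. The difference was correlated with GC content (r = 0.33 in brain, 0.23 in liver and 0.11 in muscle).

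The differences of acromegaly and of aged fish from wild type were correlated across genes, with r = 0.34 in brain, 0.45 in liver and 0.57 in muscle. Both use the same wild-type pool, and simulated unchanged groups against that pool gave r = 0.56, 0.47 and 0.55 with the spread of the low values at every gene. The covariances were 0.162, 0.40 and 0.46, against simulated values of 0.18, 0.19 and 0.26. The brain covariance of 0.162 lay below all 100 draws of that simulation (0.165 to 0.194). The liver and muscle covariances lay above all of theirs (0.180 to 0.206 and 0.241 to 0.271). With counting error alone the simulated r was 0.60, 0.46 and 0.48 and the simulated covariances were 0.0341, 0.0374 and 0.0369, so all 3 observed covariances lay above that level and brain lay between the 2 simulations. Genes at least 2-fold higher in both numbered 127 in brain, 510 in liver and 308 in muscle, where the simulation gave 235, 250.0 and 410 and independent lists would share 58.5, 196 and 81.2. Genes at least 2-fold lower in both numbered 265, 499 and 827, against 137, 194 and 270.2 in the simulation and 39.33, 99.8 and 138 for independent lists. In muscle the shared lower genes included stc1l and hbba2, and in liver the shared higher genes included vtg2, hspa5 and atf6. With counting error alone the simulation gave 24.2, 22.1 and 20.3 higher in both and 16.3, 22.4 and 21.4 lower in both. The wild-type pool could not be split, so part of any excess may come from it.

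Across tissues, 11701 genes were kept in all 3, and the examples named here were chosen after their values were seen. In acromegaly 74 were at least 2-fold higher in every tissue, where independent tissues would give 0.725, and 15 lower (0.198). The higher ones included egg genes, such as zp3.2 (chromosome 17, 2392756 to 2419739), cldnd and zar1, the glucocorticoid-induced co-chaperone gene fkbp5 and the immunoglobulin gene ighv5-8. The lower ones included ankrd37 and the parvalbumin gene pvalb9. In aged fish 168 genes were at least 2-fold higher in every tissue (6.07 if independent) and 179 lower (9.74). Many of the 168 higher rows carried no gene name, and several named small nucleolar RNAs, such as SNORD15 and SNORA65. Unnamed rows took 3.46%, 1.16% and 0.770% of the estimated counts in aged brain, liver and muscle. In wild type they took 2.91%, 0.725% and 1.02%. Named genes among the higher included clock genes (per3, ciarta, nr1d1, per1b), the stress genes atf3 and hsp70l and the DNA damage recognition gene ddb2. Those among the lower included the mitochondrial genes cox5ab and atp5a1, the trypsin gene try, srebf2 and hbba1. Genes at least 2-fold higher in 1 tissue and lower in another numbered 141 in acromegaly and 221 in aged fish. These counts compare pooled values and test no interaction of tissue and condition. The labels do not say whether the tissues came from the same fish, and whatever sets those fish apart would recur in every tissue. The numbers under independence are therefore a reference only and not a chance level.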

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

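The kidney and blood tests below were written before the kidney values were computed, but after slc13a1 and other kidney genes had been seen. Gene lists were singled out here when their medians lay outside the random lists in opposite directions in different tissues of the same condition. None of these differences between tissues was tested, since each tissue gave 1 pooled value per condition.

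In acromegaly against wild type, interferon-response genes were higher in muscle (0.28) and lower in liver (-0.36), 0.64 apart, and cholesterol synthesis was higher in liver (1.32) and lower in muscle (-0.37), 1.69 apart. Fast muscle genes were higher in muscle (0.63) and lower in brain (-0.76), 1.39 apart. Neutrophil genes (0.57 and -1.55, 2.12 apart), hepatocyte genes (0.39 and -1.04, 1.43 apart), exocrine pancreas genes (1.41 and -0.90, 2.31 apart) and pituitary genes (0.48 and -0.96, 1.43 apart) were higher in brain and lower in muscle. Without a filter the pituitary value in muscle turned to 0.077, and with a pseudocount of 0.1 it was -1.11, inside the random lists both times. Erythrocyte genes were higher in liver (0.59) and lower in muscle (-1.45), 2.04 apart. In aged against wild type, complement genes were higher in liver (0.67) and lower in brain (-0.80), 1.47 apart. Proteasome genes (0.69 and -0.51, 1.197 apart) and ribosomal protein genes (0.37 and -1.18, 1.55 apart) were higher in muscle and lower in brain. Amino acid enzymes (0.69 and -0.83, 1.52 apart) and neutrophil genes (1.204 and -1.01, 2.21 apart) were higher in liver and lower in muscle. Synapse genes were higher in muscle (1.13) and lower in liver (-0.52), 1.65 apart. At a floor of 5 FPKM, chosen after seeing the data, the acromegaly values of interferon and cholesterol genes in muscle and of erythrocyte genes in liver, and the aged value of complement genes in brain, came to lie inside the random lists. The synapse value in aged liver did so with estimated counts and after the GC correction.

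Many of these lists share a low muscle value, in acromegaly and in aged fish alike, and the wild-type muscle pool is common to both. Kidney genes had medians of -2.39 in acromegaly and -2.39 in aged muscle, with slc22a2 at 2.099, 65.6 and 6.03 FPKM in acromegaly, wild type and aged, slc34a1a at 0.296, 21.5 and 0.0574, and pdzk1 at 0.486, 20.2 and 0.330. The list has 41 kept members, 3 of them in earlier lists, and left out stc1l, cdh17 and slc5a12, which prompted it, but holds slc13a1, which had also been seen. Both medians lay below all matched random lists, while those in acromegaly brain (-0.05) and liver (-0.07) lay inside them. Of the 41 members, 40 reached FPKM of 1 in wild-type muscle but only 6 in acromegaly muscle. Most thus passed the filter through wild type, which by itself favours a low median in both comparisons. The summed FPKM of hepatocyte genes was not lower in acromegaly muscle (817, 730.04 and 796 in acromegaly, wild type and aged), which leaves that list's place in the pattern open. Kidney tissue, which in fish also forms blood, may therefore have been present in wild-type muscle libraries.

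Less blood alone cannot account for the lower kidney genes, because blood cells carry no kidney tubule genes. The kidney median of -2.39 is itself subject to the limit of the filter given above. A lower blood content besides stays open, as do effects of the conditions, which were not tested. Of 24 kidney genes with estimated counts of 1 to 60 in wild-type muscle, 3 were whole multiples of the step of 1 library.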

How the results depend on the processing

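The floor of 5, the estimated counts, the GC correction and the restriction to rows naming 1 gene were chosen after seeing the data. No paired analysis was possible because the table holds 1 pooled value per group. For the same reason these choices fixed earlier could not be tried: a fit of the 2 groups compared, the replicate number as a block, leaving out each library, robust eBayes, the highest transcript alone, the count models, camera with an estimated correlation, and duplicateCorrelation with a fish effect. Of 252 values of UPR lists under the alternatives, 243 stayed inside or outside the random lists as before, as did 2576 of 2760.0 for other lists (75 calls lost, 99 gained and 10 with the sign turned), and 4862 of 4950 for named genes stayed on their side of 2-fold. For named genes, no filter, a floor of 5 and rows naming 1 gene cannot change a value, so all 713, 700 and 693 stayed by construction. Where a value could move, 710 of 713 stayed with a pseudocount of 0.1 and 707 of 713 with median of ratios. With estimated counts 665 of 707 stayed, and with the GC correction 674 of 711. Signs nevertheless turned in 17 values of UPR lists, 111 of other lists and 15 of named genes. The 17 lay inside the random lists before and after: UPR sensors in aged liver (0.05, turning to between -0.25 and -0.37 in 3 alternatives), PERK targets in aged brain (-0.01, up to 0.19 in 3), ER-associated degradation in acromegaly muscle (0.02, down to -0.03 in 3) ER chaperones in acromegaly brain (-0.03, at most 0.0013 in 2) and 6 values for acromegaly against aged. Without a filter the counts of genes cannot differ, since a gene 2-fold apart always passes the floor of 1. Of the other 87 counts and correlations 59 stayed within 1.5 times, all of those with median of ratios (factors 0.984 to 1.02) among them.

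With a pseudocount of 0.1, which by construction widens differences between low values, genes at least 2-fold apart numbered 2391 (acromegaly against wild type), 6105 (aged against wild type) and 5730 (acromegaly against aged) in brain, 3959 in liver (acromegaly against wild type), and 3555, 5259 and 4681 in muscle. Genes alike in all 3 tissues numbered 148 in acromegaly and 630 in aged fish. With estimated counts the acromegaly counts were 373 in brain and 1299 in muscle, and the genes alike in all tissues 53 in acromegaly and 226 in aged. With a floor of 5, which keeps fewer genes, the counts in the same order (higher and lower) were 397 (218 and 179), 1878 (705 and 1173) and 1619 (1039 and 580) in brain, 1336 (896 and 440), 2795 (1341 and 1454) and 2463 (1449 and 1014) in liver, and 979 (477 and 502), 2079 (1061 and 1018) and 1764 (879 and 885) in muscle. Genes alike in all tissues then numbered 23 and 175. With rows naming 1 gene the brain counts were 586 (357 and 229), 2458 (1098 and 1360) and 2298 (1351 and 947), and 230.0 genes were alike in all aged tissues.

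With estimated counts, PERK targets (0.35) and ER-associated degradation (0.25) passed the random lists in acromegaly liver. ER-associated degradation did so in aged brain at a floor of 5 (-0.46). With the GC correction PERK targets in aged liver (0.29) no longer did. Among medians outside the random lists in either setting, signs reversed without a filter for erythrocyte genes in aged brain (0.10) and pituitary genes in acromegaly muscle (0.077). They reversed at a floor of 5 for inflammatory genes in acromegaly brain (-0.24), synapse genes in aged brain (-0.065), T and NK lymphocyte genes in acromegaly liver (0.86) and adipocyte genes in aged liver (-1.05). The GC correction reversed synapse genes in aged brain (-0.051), and estimated counts reversed znf1077 in muscle, acromegaly against aged (-0.46). For acromegaly against aged, ER chaperones in brain passed the random lists with estimated counts (0.23) and the GC correction (0.32), ER-associated degradation in brain at a floor of 5 (0.48), and PERK targets in muscle with estimated counts (-0.43) and the GC correction (-0.33). Signs there reversed for neurogenesis in liver without a filter (0.011), complement in liver with estimated counts (-0.13) and interferon genes in brain at a floor of 5 (0.22). Lost calls of other lists whose medians the text gives are stated beside those medians. The cause was not tested. As to depth, counting error alone put 126 (acromegaly) and 84.4 (aged) unchanged genes at least 2-fold apart in brain, 205 and 98.3 in liver, and 139 and 102 in muscle.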

Other observations

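All tests in this part were chosen after the result was seen. The germ line and oocyte list, fixed beforehand, had medians of 1.35, 1.501 and 1.17 in brain, liver and muscle of acromegaly fish, with 6 of 8, 10 of 13 and 9 of 16 kept members at least 2-fold higher and 0, 1 and 5 lower. As examples chosen after their values were seen, zar1, an oocyte gene, was 1.44, 4.14 and 1.25 FPKM in brain, liver and muscle and listed at 0 in wild type, zp3b was 4.15 against 1.9995 in brain, and cldnd was 5.27, 4.76 and 10.2 FPKM, with 0.491 in wild-type muscle and 0 in the other wild-type tissues. In aged fish zar1 stood at 3.83 in liver and 5.05 in muscle but at 0.0444 in brain. Other single genes went the other way: sycp1, of the synaptonemal complex, was 4.99 in wild-type muscle (1.60 in acromegaly, 0.345 in aged), and tekt1, of cilia and sperm tails, was 5.02 in wild-type muscle, 2.03 in wild-type liver and 1.58 in wild-type brain (0.0711, 0.0522 and 0.418 in acromegaly). Some egg and germ line genes with estimated counts of 1 to 60 were whole multiples of the step of 1 library. In acromegaly they numbered 6 of 18 in brain, 8 of 16 in liver and 12 of 20 in muscle. The shares over all rows with such counts were 3.34%, 7.84% and 9.05%. In wild type they numbered 2 of 10, 5 of 11 and 1 of 13 (4.197%, 5.83% and 7.07% of all rows). In aged fish they numbered 0 of 5, 3 of 21 and 2 of 21 (0.939%, 3.94% and 1.75%). The share was largest in acromegaly in every tissue, close to wild type in liver and far above it in muscle. Many of these egg and germ line values in acromegaly thus came from 1 library.

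The immunoproteasome gene psmb9a was listed at 0 in acromegaly and wild type of every tissue and at 2.43, 25.0 and 45.005 FPKM in aged brain, liver and muscle. Fast muscle genes in brain summed to 0.0999% of their level in muscle in acromegaly, 0.363% in wild type and 0.0233% in aged fish.

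The higher ER chaperone genes in acromegaly liver were weighed against 3 explanations. More exocrine pancreas, a tissue rich in these chaperones, is argued against by its list median of -0.047, and scaling of the whole column by matched random lists, whose upper bound was 0.25 against the observed 0.53. More egg-yolk-producing females in the acromegaly group cannot be told apart from the condition: vtg2 differed by 11.52 on the log2 scale, and the labels give no sex. Growth hormone excess itself stays open and was not tested.

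Aged fish had 347 genes at least 2-fold apart in the same direction in all 3 tissues, where independence would give 15.8. Fish shared between tissues would raise the number above that reference. A GC trend is argued against as the whole cause, since 256 such genes were left after GC correction (222 in both sets, 10.9 under independence). The correction also left out rows with a very short transcript or none, so part of the fall from 347 may come from that. For the clock genes among them, medians of genes high after dawn and after dusk lay 1.42 apart in brain, 2.81 in liver and 2.601 in muscle, against -0.48, 0.94 and -0.05 in acromegaly. The dusk medians were -0.91 in aged liver and -1.26 in aged muscle, below the random lists, but 0.05 in aged brain, inside them. The gap in brain thus came from the dawn genes alone (1.47). The dawn list was written after the values were seen. Its members per1b, per3, nr1d1, ciarta, ciartb, dbpa and tefa are themselves among the 347 genes, so a high dawn median was largely fixed by that choice. Collection at another hour may explain these clock genes, but the gap cannot decide it, and the dusk list had only 4 or 5 kept members. An effect of age on the clock, and on the other genes, stays open and was not tested.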
